A study of Mus musculus with 10 samples.

How the data were processed

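10 RNA-seq libraries were made from total RNA of conditionally immortalized mouse renal proximal tubule cells, 1 library for each of 10 groups. Per the labels' protocols, cells were transfected with siRNA at 33 °C and then kept at 37 °C without interferon gamma, RNA was isolated with a column kit and a DNase step, and reads of 100 nt were sequenced on a HiSeq 2500. Library strandedness and the time in culture are not given in the sources used here. Per the submitters' processing notes, the build was mm10 and TopHat2, Cufflinks and Cuffdiff were used, with no version given; settings and the gene annotation are not given in the sources used here.

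The authors deposited FPKM values, with Cuffdiff's status, p-values and q-values per the file headers, in 3 tables of all genes (46509 rows each) for libraries 8, 9 and 10 against library 7. The deposited p-values and q-values were copied as the authors' own, since a test of 2 single libraries compares those libraries and not the conditions. The FPKM values of library 7 differed between the 3 tables by near-constant factors of 1.00334 and 1.00116, with 1 of 11729 genes off by over 1 percent, so each table was scaled on its own and ratios were formed within a table. The authors also deposited FPKM values of 4 libraries each for 2 lists of selected genes, 1852 genes for libraries 1, 2, 5 and 6 and 1637 genes for libraries 3, 4, 7 and 10. As checked on the values, the first list holds genes with a log2 ratio above 0.5 in 2/1 and a value above 0 in library 1, and the second holds genes with an absolute log2 ratio above 0.5 in both 4/3 and 10/7 and no value at 0. Both lists join tables that were scaled separately, so levels were compared only within a pair of libraries. Values of libraries 1 to 6 for genes outside those lists were not analysed here. In the first list 1 symbol had been turned into a date by a spreadsheet, and genes were matched by identifier. The deposited fold column was not used, and ratios were computed anew from FPKM.

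No total counts are given, so the depth of each library is unknown. In weakly expressed genes (FPKM under 0.3 in both libraries) the ratio of 2 libraries is close to a ratio of small whole numbers times what 1 fragment is worth. On that basis the depth of libraries 8, 9 and 10 was 0.883, 0.920 and 0.920 of that of library 7, with 72.8%, 69.5% and 59.5% of 2895, 2879 and 2868 such genes within 0.03 (log2) of a whole-number ratio against 40.2% of the axis. The summed FPKM was 508824, 506809 and 510607 in libraries 8, 9 and 10. No counting interval was computed. Rows listed at exactly 0 in 1 library included Gapdh, so they were treated as possible failed estimates and no fold is given for them, except that the computed difference of Snhg9 is printed where its flag is described.

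Ratios were log2((a + 1)/(b + 1)) with a pseudocount of 1 FPKM. A gene counted as measured with FPKM of 1 or more in at least 1 of the 2 libraries, as past the size rule at a log2 ratio of 1 either way, and, as a list member, as higher or lower past 0.58 either way. With 1 library per group no test between conditions was made. The unit matched what had been planned for, so the planned rules were kept. Before the data were examined, 30 gene lists were fixed, and for each list with at least 3 measured members the median was placed among 10000 random lists of the same size, drawn with replacement within 10 bins of mean log2 FPKM. The percentile describes these libraries and is no p-value. Named genes followed a rule fixed at the same time. Foxo1 and Foxo3 came first, then the 10 highest and 10 lowest ratios among rows with 1 symbol, the authors' status OK and FPKM of 5 or more in at least 1 library, leaving out symbols that start with Mir, Snor, Gm and a digit, n-R or Rn, that end in Rik, or that are histone or mitochondrial genes. Up to 4 members per list with the largest absolute ratio followed. In the 2 lists of joined effects the rule took the 10 genes with the largest smaller effect of the same sign and the 5 with the largest difference each way; these lists give no status, so that filter did not apply. Some genes that these rules select are not reported here. Genes the authors set apart were named as chosen by them on these libraries.

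The 3 comparisons with library 7 share their control. Unchanged libraries were simulated 100 times from the mean FPKM of the 10890 genes without FAIL status, a listed 0 or a left-out symbol, with Poisson counting error at the relative depths above, an estimated worth of 1 fragment of 0.0425 FPKM per kb, and a library spread of 0.0890 (log2) fitted to the observed robust spread. Genes past 0.58 in both ratios of a pair were counted in the same simulated libraries. Contrasts with no library in common (8/7 with 10/9, 9/7 with 10/8, 10/7 with 9/8) were formed by subtracting ratios. The worth of 1 fragment is a rough estimate from 598 genes with a single annotated transcript.

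The rules were tested on simulated data for each of the 3 comparisons, over 11729 genes with 200 changed. The size rule recovered 87%, 88% and 90% of 100 genes changed by 1.5 (log2) in the simulated 8/7, 9/7 and 10/7, and 99%, 96% and 100% of 100 genes changed by 3. It passed 0%, 0.0173% and 0% of unchanged genes. The simulated libraries held counting error and a normal library spread but no failed estimates, so these shares do not cover rows listed at 0. Of 200 unshifted lists of 24 genes, 4%, 3.5% and 4.5% lay outside the middle 95% of 1000 random lists each, and 100% of lists shifted by 0.3 lay above it. Those lists were drawn at random, so the test does not cover lists whose members vary together.

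Gene coordinates and exons were taken by identifier from GENCODE M21 on the same mm10 assembly. Of the identifiers, 45998 were found there and the span of 87.5% of these lay within the locus given in the tables. Exonic bases shared with another gene were computed from the same annotation, on either strand, since strand-specific counting is not stated. The alternatives tried were other pseudocounts (0.1 and 5 FPKM), other filters on low values, centring on the median, rows of status OK only, a size rule of 0.58, the authors' q, Spearman correlation, the mean in place of the median of a list, and random lists not matched on expression. Centring could not be applied to the 2 selected lists, which do not hold all genes. Chosen after seeing the data were counts without rows listed at 0 or without the left-out symbols, library 8 as a control, comparisons with no library in common, and further FPKM filters on the selected lists. Computations used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9.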

Results

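RNA sequencing was performed on 10 libraries of conditionally immortalized mouse renal proximal tubule cells, the epithelial cells that reabsorb most of the glomerular filtrate. Each library was the only one of its group, so no difference below has a replicate check, and no test between conditions was made. Libraries 1 and 2 received no siRNA and no H2O2, with Wnt diluting buffer or with Wnt3a at 20 ng/mL. Libraries 3 and 4 received Wnt3a without H2O2, with scramble siRNA or with siRNA to both FoxO1 and FoxO3. Libraries 5 and 6 received 100 uM H2O2 and no siRNA, and library 6 also received Wnt3a; the Wnt entry of library 5 holds no treatment. Libraries 7, 8, 9 and 10 all received H2O2 and Wnt3a, with scramble siRNA, FoxO1 siRNA, FoxO3 siRNA and both siRNAs. FoxO1 and FoxO3 are forkhead transcription factors restrained by insulin and AKT signalling. Wnt3a is a ligand that stabilises beta-catenin, and H2O2 served as the oxidative stress. The cells came from mice of mixed strain, labelled TbRII floxed, crossed with a mouse that carries a conditional immortalizing gene.

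Values were FPKM, fragment counts scaled by transcript length and library size. The size scaling differed slightly between the tables, and its settings are not given. Total fragments per library are not known here, and weakly expressed genes placed the depth of libraries 8, 9 and 10 at 0.883, 0.920 and 0.920 of that of library 7. Ratios below are log2((a + 1)/(b + 1)) of FPKM, which understates the change of weakly expressed genes, and are written 8/7 for library 8 over library 7. Among genes with FPKM of 5 or more, the robust spread of the ratios was 0.118 for 8/7, 0.164 for 9/7 and 0.127 for 10/7.

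The targeted genes were examined first. Foxo1 (ENSMUSG00000044167, mm10 chromosome 3, 52268336 to 52353221) had an FPKM of 7.92 in the scramble library and 3.66 in the FoxO1 siRNA library, a ratio of -0.94, or 46.2% of the scramble level. It stood at 4.67 with both siRNAs, 58.8% of the scramble level, and at 8.54 in the library labelled FoxO3 siRNA. Foxo3 (ENSMUSG00000048756, chromosome 10, 42181841 to 42276755) had an FPKM of 19.7 in the scramble library and 19.9 in the library labelled FoxO3 siRNA, a ratio of 0.01. Foxo3 was thus not lower in the library whose label says that it was targeted. It stood at 17.4 with both siRNAs, a ratio of -0.17, close to the -0.14 of the FoxO1 siRNA library, which had no FoxO3 siRNA. Every direction given below for library 9 is therefore one of the library labelled FoxO3 siRNA, and the joint siRNA libraries are known to have a lower Foxo1 level only in library 10.

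**Figure D1:**
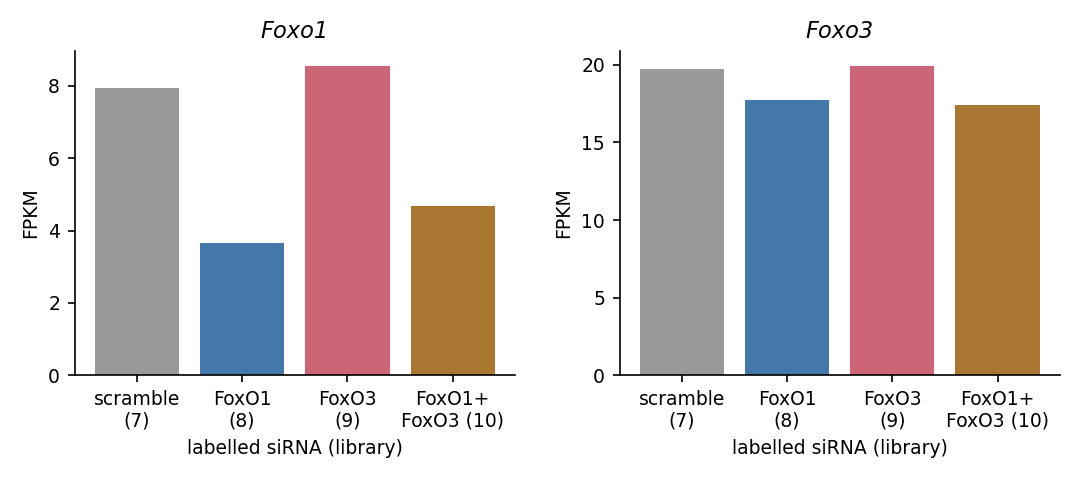
FPKM of Foxo1 (left) and Foxo3 (right) in the 4 libraries that received H2O2 and Wnt3a; each bar is 1 library, named by its siRNA label. The scramble bars are library 7 as scaled with library 10. Foxo1 was at 3.66 with FoxO1 siRNA and 4.67 with both siRNAs against 7.95 with scramble siRNA, while Foxo3 lay between 17.4 and 19.9.

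The comparison of library 8 with library 7 asked which transcripts change with FoxO1 siRNA in cells given H2O2 and Wnt3a. Foxo1 itself was the lowest-ranked gene, and the highest-ranked genes held several interferon-inducible ones. Apol9a, an apolipoprotein L family gene, had a ratio of 1.20, Tgtp2, an interferon-induced GTPase, 1.07, Oasl2, an oligoadenylate synthetase-like gene, 1.01, and Xaf1, an apoptosis-associated factor induced by interferon, 0.94. Tlr6, a Toll-like receptor, had a ratio of 0.96 and Selo, a mitochondrial selenoprotein, 1.23. Txnrd1, thioredoxin reductase, was ranked highest, but it was listed at 0 in library 7 and at 126 FPKM in library 8, and the locus given for its row spans 95 bp, far less than the annotated gene; no fold is given for it. The microRNA row mmu-mir-3535, which shares 56.5% of its exonic bases with Ncl, was also listed at 0 in library 7, and mmu-mir-703 had a ratio of 0.93. Taf9, with a ratio of 1.31, shares 73.8% of its exonic bases with Ak6 on the same strand and was uncertain for that reason. After Foxo1, the lowest were Cox6b2 at -0.90, Smim4 at -0.82, Slc15a4, an endolysosomal peptide transporter, at -0.80, Sepp1, the plasma selenium carrier, at -0.79, Rtn1 at -0.78, Tmem59 at -0.74, Stxbp6 at -0.69, E2f3, a cell cycle transcription factor, at -0.66 and S100a3 at -0.64.

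Of 24 interferon-stimulated genes measured in 8/7, 7 were higher by at least 0.58 and 0 lower, and all 24 ratios were above 0. Their median of 0.37 lay at percentile 100 of 10000 random lists of the same size matched on expression, whose middle 95% ran from -0.08 to 0.06. Ifi44 had a ratio of 1.26, Mx2 0.81 and Rsad2 0.78. The NRF2-driven antioxidant list was the other one outside the middle 95% of random lists, with a median of -0.08 at percentile 0.04. Blvrb had a ratio of -0.40, Osgin1 -0.31 and Abcc4 -0.23, and the only member higher by 0.58 was the Txnrd1 row listed at 0, which turned the mean of the list to 0.21. Of 27 known FoxO target genes, 0 passed 0.58 either way, and their median was 0.04, with Pik3ip1 at 0.37, Txnip at 0.36 and Sesn3 at -0.33. The p53 target, pro-apoptotic, anti-apoptotic, cell cycle and Wnt target lists had medians from -0.05 to 0.02 and no member past 0.58.

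Of 12006 genes with FPKM of 1 or more in either library, 77 were higher and 66 lower by at least 2-fold, 143 in all. Of these, 94 were listed at exactly 0 in 1 library and 108 had symbols that the ranking leaves out. Those are small RNA, predicted, histone, mitochondrial or Rik symbols, any symbol starting with Rn, and rows with several symbols. Without both kinds and without FAIL rows, 12 were higher and 6 lower. In the authors' deposited table for 8/7, 0 of 13302 tested genes had q at or under 0.05, 164 had an unadjusted p under 0.05, and the smallest q, 0.133, was held by Foxo1, Oasl2, Apol9a, Tspan8 and 3300005D01Rik. That test compared 2 libraries, not conditions. Gapdh, which every cell uses, was listed at 0 in library 7 and at 931 FPKM in library 8, so an exact 0 in these tables can be a failed estimate.

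The comparison of library 9 with library 7 asked the same of FoxO3 siRNA, with the limit that Foxo3 was not lower. Aldh1a1, which makes retinoic acid from retinal, went from 25.7 to 84.6 FPKM, a ratio of 1.68, and its paralog Aldh1a7 had a ratio of 1.55. These neighbours on chromosome 19 are similar in sequence, so reads may have been shared between them. Dhrs3, a retinal reductase, was lower at 20.2 against 47.8 FPKM, a ratio of -1.20. Aqp1, the water channel aquaporin 1, had a ratio of 1.32 and Cd55, decay accelerating factor, 1.65, from an FPKM of 0.94. Saa3, an acute phase protein, had a ratio of 1.35, Selo 2.17 and Taf9 1.28. The other 3 of the highest were Rpl39-ps, a ribosomal protein pseudogene, at 1.41, AC120402.1 at 2.47 and AL596185.1, which was listed at 0 in library 7. Among the lowest were Zhx2, a transcriptional repressor, at -1.43, the chemokines Ccl5 at -1.40 and Ccl17 at -1.16, Aldh1l2, a mitochondrial folate enzyme, at -1.35, Trib3, a stress-induced pseudokinase, at -1.27, Ciart, a circadian repressor, at -1.23 and Col4a3, a basement membrane collagen chain, at -1.21.

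Interferon-stimulated genes went the other way from library 8. Of 23 measured in 9/7, 0 were higher and 9 lower by at least 0.58, and their median of -0.47 lay at percentile 0 of random lists. Ifit1 had a ratio of -1.26, Isg15 -1.18, and Irf7 and Oasl2 both -1.15, while Ifit2 at 0.23 and Ifit3 at 0.50 lay above 0. Of 22 unfolded protein and integrated stress response genes, 4 were lower and 0 higher, namely Trib3, the glutathione-degrading enzyme Chac1 at -0.89, the lipoprotein receptor Vldlr at -0.79 and asparagine synthetase Asns at -0.71. The list's median of -0.06 lay at percentile 16.1 and its mean of -0.21 at percentile 0.89 of random means; Atf4 stood at -0.46, and Psat1, Phgdh and Sesn2 at -0.27, -0.24 and -0.18. In the matrix and TGF-beta response list, 4 of 27 members were lower and 1 higher. Connective tissue growth factor Ctgf went from 225 to 114 FPKM, a ratio of -0.97, the gelatinase Mmp9 had a ratio of -0.83, the growth factor chain Pdgfb one of -0.62, and the matrix protein Postn one of 0.85. The list's median of -0.04 lay at percentile 37.9 and its mean of -0.15 at percentile 1.62. Ctgf shares 23.2% of its exonic bases with Gm15270 on the opposite strand, and whether reads were counted by strand is not known. In the cytokine and chemokine list, 3 of 19 were lower and 1 higher, with Ccl5, Cxcl10 at -1.03 and Vcam1 at -0.70 lower and Cxcl5 higher at 0.73.

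Of the 25 lists with at least 3 measured members, 10 had a 9/7 median outside the middle 95% of random lists. For lists of genes drawn at random 1.25 would lie outside. Genes of a list may vary together and some lists share members, so 1.25 is no chance expectation for single libraries. Of 16 tubular injury genes 1 was lower by 0.58, and the list had a median of -0.20 at percentile 0.010, with Vcam1 at -0.70, Krt8 at -0.58, Clu at -0.50 and Spp1, which went the other way, at 0.51. Wnt target genes had a median of -0.19 at percentile 0.080 with 1 member, Id2, past 0.58 at 0.62, and cholesterol synthesis genes a median of -0.14 at percentile 0.28, with Insig1 at -0.58. Immediate early genes had a median of 0.20 at percentile 99.9, with Egr1 at 0.75 and Fos at 0.68. Known FoxO targets lay slightly above 0, with a median of 0.15 at percentile 100 and 0 of 27 past 0.58. NRF2-driven genes had a median of 0.12 at percentile 100, with Nqo1 at 0.66 and Slc7a11, the cystine transporter, at -0.70. The medians of the other antioxidant, p53 target and autophagy lists, from 0.05 to 0.07, lay at percentiles from 98.7 to 98.8. Their members past 0.58 were Txnrd2 at -0.62 and Btg2 at 0.89. With the mean in place of the median, 4 of the 10 lists stayed outside: tubular injury, interferon-stimulated, cholesterol synthesis and immediate early genes. The Wnt target list, with a mean of -0.028, and the FoxO target, NRF2-driven, other antioxidant, p53 target and autophagy lists lay inside. The last 3 also lay inside with random lists not matched on expression.

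Of 12045 genes measured in 9/7, 89 were higher and 97 lower by at least 2-fold, 186 in all. Without FAIL rows, rows listed at 0 and the symbols that the ranking leaves out, 21 were higher and 31 lower. The authors' deposited table held 19 genes with q at or under 0.05, 7 higher and 12 lower, all with q = 0.0352, of 13389 tested, and 322 with an unadjusted p under 0.05. These 19 were chosen by the authors on these libraries. Aqp1, Aldh1a1, Aldh1a7, Cd55, Dhrs3, Ccl17, Aldh1l2, Ctgf, Ifit1 and Oasl2 were among them. That test compared 2 libraries, not conditions.

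The comparison of library 10 with library 7 paired both siRNAs with scramble siRNA. Postn, a secreted matrix protein, went from 29.1 to 54.6 FPKM, a ratio of 0.89, and was 1 of 2 genes at the smallest q of the authors' deposited table, 0.334. Sepp1 had a ratio of 1.62, whereas its 8/7 ratio was -0.79. Aldh1a1 had a ratio of 0.73 and Cpz, a carboxypeptidase that binds Wnt proteins, 0.79. Taf9 stood at 1.49, the ribosomal pseudogene Rpsa-ps2 at 0.99, Itfg2 at 0.86, the orphan receptor Gpr19 at 0.84 and Fam129c at 0.81, and AC123686.1, which lies wholly within exons of Gm7291 on the opposite strand, was listed at 0 in library 7. The lowest were mmu-mir-703, listed at 0 in library 10, the noncoding RNA Hotairm1 at -1.13, the sterol reductase Tm7sf2 at -0.86, Gemin4 at -0.75, Cklf at -0.74, Tmem59 at -0.74, Gad1os at -0.70, Eif3s6-ps2 at -0.70, the leukotriene receptor Cysltr1 at -0.70 and Nme3 at -0.68. Gemin4 shares 89.8% of its exonic bases with Glod4 and Nme3 87.1% with Mrps34, so both were uncertain, as were Fam129c, which shares 21.8% with Pgls, and Hotairm1.

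Cholesterol synthesis genes were the list farthest below random lists in 10/7. Their median of -0.22 lay at percentile 0, with Nsdhl and Mvd at -0.33 and -0.29, and 0 of 19 passed 0.58. The cytokine and chemokine list had a median of -0.17 at percentile 0.010, with Ccl5 at -0.57 and Il34 at -0.53. The matrix list had a median of -0.10 at percentile 0.17, although Postn went the other way, and the tubular injury list a median of -0.09 at percentile 0.91. NRF2-driven genes had a median of 0.11 at percentile 99.99, with Gclc at 0.42 and Nqo1 at 0.42, and known FoxO targets a median of 0.07 at percentile 99.7. Of 23 interferon-stimulated genes, 0 were higher and 2 lower, Isg15 at -0.65 and Bst2 at -0.61, with a median of -0.11 at percentile 1.24. With the mean in place of the median, only the cholesterol list of these 7 stayed outside; the FoxO target, NRF2-driven, tubular injury, matrix, cytokine and interferon lists lay inside. Of 7 heat shock genes Hspb1 alone passed 0.58, at -0.66. Of 12062 genes, 77 were higher and 71 lower by at least 2-fold, 148 in all. The counts were 10 and 7 without FAIL rows, rows listed at 0 and the symbols that the ranking leaves out. The authors' deposited table had 0 of 13356 tested genes with q at or under 0.05 and 201 with an unadjusted p under 0.05.

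Lists of markers of other cell types were checked in libraries 7 to 10. Of the fibroblast list only Fbln1 was measured, at ratios of 0.01, 0.24 and 0.14 in 8/7, 9/7 and 10/7. Of the leukocyte list Cd68 and Csf1r and of the 5 podocyte genes Synpo and Wt1 were measured, with no ratio past 0.58. In library 7 Synpo stood at 28.2 FPKM, Fbln1 at 6.17, Cd68 at 5.88 and Wt1 at 4.21, so some of these markers were clearly detected. Of the endothelial and distal nephron lists 0 members were measured. Of 28 proximal tubule markers 6 were measured, and Aqp1 was the only one past 0.58 in any of the 3 comparisons. RNA interference machinery genes, a control for siRNA load, had medians of 0.03, 0.03 and -0.02, and housekeeping genes of -0.04, -0.05 and -0.01.

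The 3 siRNA comparisons were then set side by side. They share library 7, so chance alone makes their ratios correlate across genes. The correlation across 12352 genes, which are not independent replicates, was 0.46 for 8/7 with 9/7, 0.47 for 8/7 with 10/7 and 0.47 for 9/7 with 10/7. In 100 simulated sets of unchanged libraries sharing one control, the mean correlation was 0.49 and the mean covariance 0.0121; the spread of those libraries was fitted to the observed spread, any effects included. Over the 10890 genes without FAIL status, a listed 0 or one of the symbols left out of the ranking, the correlations were 0.24, 0.41 and 0.46 and the covariances 0.00964, 0.0130 and 0.0196. All 3 correlations lay below the simulated range of 0.469 to 0.511. The simulation gave every library the same spread, while the observed spreads of 8/7, 9/7 and 10/7 were 0.118, 0.164 and 0.127. The range need not hold for libraries of unequal spread. The simulated covariances ran from 0.0114 to 0.0129, below those of 8/7 with 10/7 and 9/7 with 10/7 and above that of 8/7 with 9/7. The 2 measures thus place both pairs with library 10 on different sides of the simulation. Comparisons with no library in common gave correlations over the same genes of 0.09 for 8/7 with 10/9, 0.22 for 9/7 with 10/8 and 0.14 for 10/7 with 9/8. Among the 10705 of those genes measured in both 9/7 and 10/7, 28 were higher by 1.5-fold in both and 17 lower in both. For 8/7 and 10/7 the numbers were 9 and 13 of 10696 genes, and for 8/7 and 9/7 they were 10 and 11 of 10684. The simulated unchanged libraries, which share a control and cover all 10890 genes, gave at most 6 in any pair and direction. Their spread is an assumed normal one with few large ratios, so the excess was not traced to siRNA. All 19 genes called by the authors in 9/7 had the same direction in 10/8, with a median along that direction of 0.33 against 1.15 in 9/7.

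**Figure D2:**
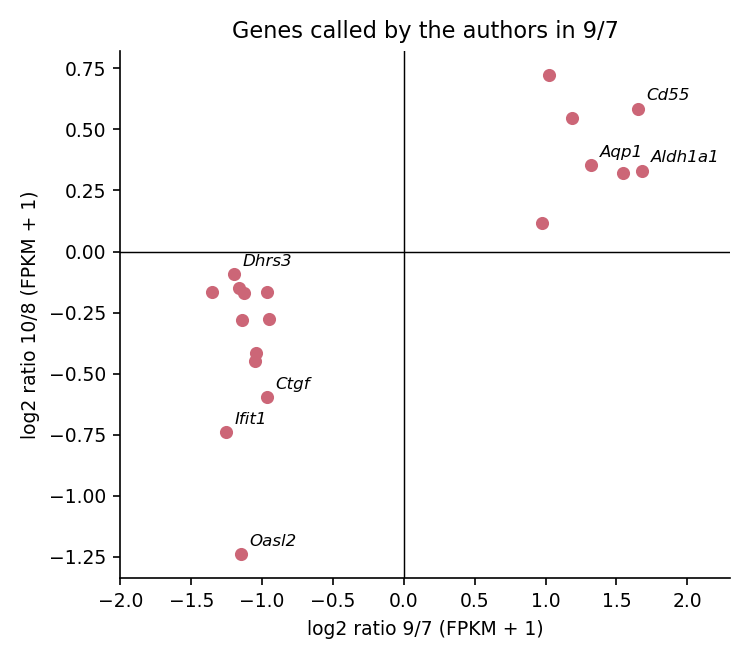
Log2 ratios (FPKM + 1) of the 19 genes called by the authors in library 9 against library 7 (x axis) and in library 10 against library 8 (y axis), 2 pairs with no library in common; each point is a gene. All 19 points have the same sign on both axes, 7 of them above 0 and 12 below.

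The Wnt3a response without H2O2 (2/1) was compared with that under H2O2 (6/5), to see which genes Wnt3a raises under oxidative stress. The authors' table holds 1852 genes, every one with a log2 ratio above 0.5 in 2/1 before the pseudocount, so it shows genes higher in 2/1 only, and counts describe that list. A ratio above 0 in 2/1 is thus fixed by the selection, and members of a gene list outside the table are not seen. Lcn2, the injury-associated lipocalin, had ratios of 5.58 in 2/1 and 6.45 in 6/5. It went from 0.11 to 51.8 FPKM without H2O2 and from 0.80 to 157 FPKM with it. Without the pseudocount its fold was larger in 2/1, so the order of its ratios comes from the pseudocount. The neutrophil chemokines Cxcl5 and Cxcl1 had 5.11 and 7.30, and 3.31 and 5.08. Axin2, a standard Wnt/beta-catenin feedback target, went from 0.64 to 12.5 FPKM without H2O2 and from 1.01 to 20.6 FPKM with it, ratios of 3.04 and 3.43. Ccl2 had ratios of 2.41 and 3.39, Cxcl3 2.38 and 2.74, complement C3 2.35 and 4.00, the prostaglandin transporter Slco2a1 2.31 and 3.37, Ccl7 2.27 and 4.32, and the transcription factor Cebpd 2.21 and 3.25.

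The effects that grew most under H2O2 were those of Saa3, with ratios of 0.38 and 3.86, of Nos2, the inducible nitric oxide synthase, with 0.78 and 3.44, and of Cxcl5, Ccl7 and the lipopolysaccharide binding protein Lbp, with 1.92 and 3.70. Both Saa3 and Nos2 lay below 1 FPKM in libraries 1, 2 and 5 and reached 15.1 and 9.94 FPKM in library 6. Of the 23 cytokine, chemokine and NF-kB genes, 15 were in the list, all 15 had ratios above 0 in 6/5, and 14 had a larger ratio there than in 2/1. Of the 11 with FPKM of 5 or more, 10 had the larger ratio in 6/5. The 14 include Il1a, listed at 0 in library 5 and at most at 0.057 FPKM elsewhere. They also include Csf2, from 0.047 to 1.75 and from 0.30 to 8.00 FPKM, whose fold was larger in 2/1 without the pseudocount. Of 30 Wnt target genes 9 were in the list, and 6 of these had the larger ratio in 6/5, with Tcf7 at 1.28 and 1.04 and Apcdd1 at 0.54 and 0.99. The 6 include Rnf43, from 0.095 to 0.67 and from 0.30 to 1.14 FPKM, whose fold was larger in 2/1 without the pseudocount. They also include Nkd1 and Sp5, which stayed below 1 FPKM in all 4 libraries. The largest differences the other way were Snhg9, listed at 0 in library 6, Selo at 2.09 and 0.77, Rpl39-ps at 1.32 and 0.11, Gga3 at 0.50 and -0.69 and Cep131 at 0.44 and -0.62. Selo shares 26.7% of its exonic bases with Tubgcp6 on the opposite strand.

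Of the 1852 genes, 1009 had a ratio above 0 in 6/5, 54.5%, and 46 passed 2-fold in both. The share was larger among more strongly expressed genes, 82.3% of the 209 genes with FPKM of 5 or more, and 1270 of the listed genes were below 1 FPKM in all 4 libraries. The authors noted 28 genes as raised and 13 as suppressed by Wnt3a under oxidative stress, chosen on these same libraries and so not independent evidence. Of the 28, 27 had a larger ratio in 6/5 than in 2/1 and 9 reached 5 FPKM, while all 13 had ratios below 0 in 6/5 and 0 reached 5 FPKM.

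**Figure D3:**
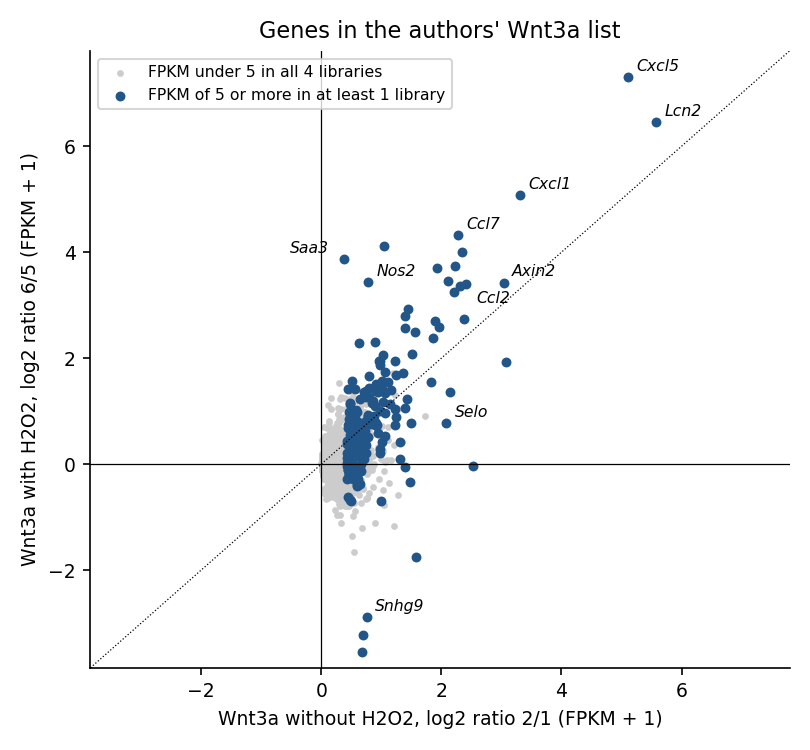
Log2 ratio (FPKM + 1) for Wnt3a without H2O2 (library 2 over 1, x axis) and with H2O2 (library 6 over 5, y axis) for the 1852 genes of the authors' list; each point is a gene, dark where FPKM reached 5 in at least 1 library, and the dotted line marks equal ratios. Cxcl5 at 7.30, Lcn2 at 6.45 and Cxcl1 at 5.08 have the highest labelled y values and lie above that line, Lcn2 only because of the pseudocount. Some unlabelled dark points are symbols left out of the ranking.

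The joint siRNA effect without H2O2 (4/3) was compared with that under H2O2 (10/7). This table holds 1637 genes, all with an absolute log2 ratio above 0.5 in both comparisons before the pseudocount, and neither Foxo1 nor Foxo3 is among them. Foxo1 passed that bound in 10/7, at -0.77 before the pseudocount. If the list is complete and Foxo1 was not listed at 0, Foxo1 did not pass 0.5 in 4/3. A lower Foxo1 level in library 4 is therefore not shown. Postn, with ratios of 0.99 in 4/3 and 0.89 in 10/7, and Aldh1a1, with 0.79 and 0.73, were higher with joint siRNA in both settings. Also above 0 in both were Cpz at 0.73 and 0.79, Aqp1 at 0.63 and 0.68, the transcription factor subunit Rfxap at 0.62 and 0.69, Sepp1 at 0.61 and 1.62, and the carboxylesterases Ces2g at 0.80 and 0.58 and Ces2e at 0.58 and 0.73. Dhrs3 was lower in both, at -0.71 and -0.63, and so was Rpph1, the RNA of ribonuclease P, at -1.96 and -1.34. Rpph1 shares 73.0% of its exonic bases with Ccnb1ip1 and was uncertain. Ces2g and Ces2e are close paralogs, as are Aldh1a1 and Aldh1a7, so reads may have been shared within each pair.

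Among effects with the higher ratio under H2O2, the largest differences were those of Sp140, at -0.69 and 0.49, and Wnk4, a kinase of renal salt transport, at -0.55 and 0.52, which were below 0 without and above 0 with H2O2. Sepp1, Rpph1 and RP24-299A7.2, the last at -0.76 and -0.44, were next in that direction. Gemin4 at 0.49 and -0.75 and the cytokine Il34 at 0.48 and -0.53 went from above to below 0. Sprr1a, with ratios of 1.30 and 0.38, and Col11a1, with 1.00 and 0.34, were higher mainly without H2O2. Over the whole list, 867 of 1637 genes had the same sign in both settings and 3 passed 2-fold in both, 2 higher and 1 lower. Among the 48 genes with FPKM of 5 or more the share was 83.3%, 24 higher in both and 16 lower in both. The list held 1 of the 36 known FoxO targets and 3 of the 23 cytokine genes, Ccl5 at -0.74 and -0.57, Cxcl2 and Il34. The 4 genes of interest that the authors set apart on these libraries, Pagr1a, Hpx, Cyp27b1 and Prkcz, stayed below 1 FPKM in all 4 libraries except Pagr1a, at 3.43 FPKM in library 10.

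**Figure D4:**
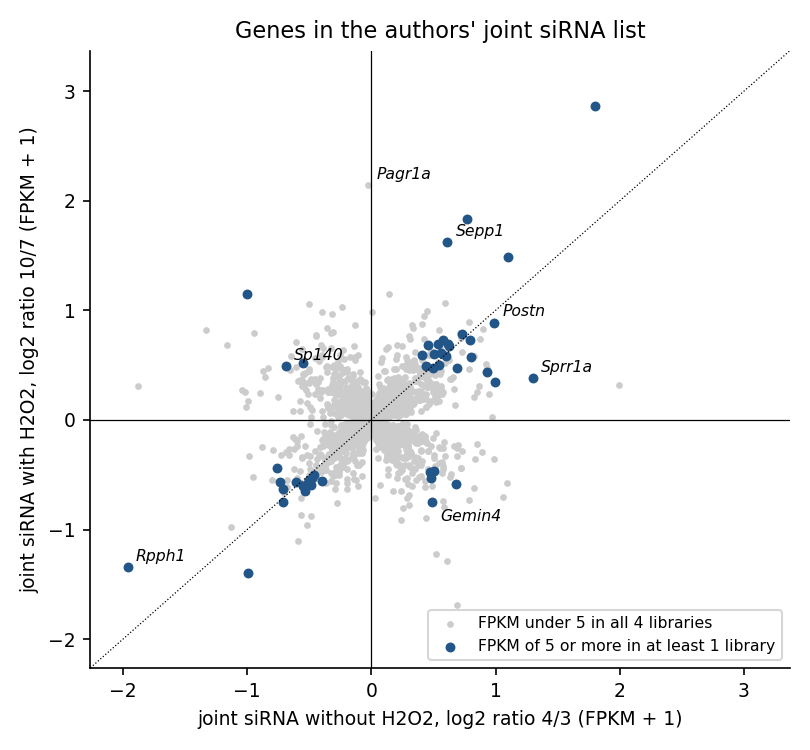
Log2 ratio (FPKM + 1) for joint FoxO1 and FoxO3 siRNA without H2O2 (library 4 over 3, x axis) and with H2O2 (library 10 over 7, y axis) for the 1637 genes of the authors' list; each point is a gene, dark where FPKM reached 5 in at least 1 library, and the dotted line marks equal ratios. Of the 48 dark points 40 have the same sign on both axes, and some unlabelled ones are symbols left out of the ranking.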

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

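The tests of FPKM of 5 or more among interferon-stimulated genes, of list selection over 75 genes and of scaling of the 6/5 pair were fixed before their results were seen; the other tests in these paragraphs were chosen after. The interferon gamma test replaced an earlier one, on a single odd library, once member values had been seen, and its 5 genes and bound were set then. Each contrast rests on 1 library a side, so none of the differences below was tested.

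Interferon-stimulated genes had a higher median in the FoxO1 siRNA library and a lower one in the library labelled FoxO3 siRNA, and the 9/7 median minus the 8/7 median was -0.84. Weak expression alone is argued against, since the 16 members with FPKM of 5 or more had an 8/7 median of 0.31 and the 14 such members in 9/7 one of -0.26. Both lay outside the middle 95% of matched random lists. The filter asks for 5 FPKM in either library. Oasl2, from 3.46 to 7.97 FPKM, and Usp18, from 3.98 to 7.28 FPKM, passed it in 8/7 only through library 8, which favours a higher 8/7 median. Interferon gamma left in the medium cannot be told apart: the median of 5 members known first as its targets lay nearer 0 than that of the other members, by 0.34 in 8/7 and by 0.44 in 9/7, but these 5 were picked with the values in view. A response to the siRNA molecules cannot be told apart from one to FoxO1, since no library holds another siRNA to the same target; the RNA interference machinery list, with an 8/7 median of 0.028, does not decide it. In library 10 Foxo1 was also lower, at 58.8% of the scramble level, but the list's 10/7 median was -0.11, with 0 members higher and 2 lower by at least 0.58. That library also received FoxO3 siRNA, so it does not decide the matter. A FoxO1 effect on interferon signalling stays open as an untested biological hypothesis.

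The library labelled FoxO3 siRNA had no lower Foxo3 and yet, under the planned rules, had the most genes past 2-fold against the scramble library (186), though library 10 had more with a pseudocount of 5 FPKM (59 against 51). A swap of labels among libraries 7 to 10 cannot be told from Foxo3. The lowest Foxo3 ratio of another library against library 9 was -0.19, so no library from 7 to 10 had clearly lower Foxo3, whatever its label. A swap among these libraries would therefore not by itself account for the missing Foxo3 drop. Foxo1 stood at 46.2% and 58.8% of the scramble level in libraries 8 and 10 and at 108% in library 9. These values, from 1 library each, argue against a swap of library 8 or 10 with library 7 or 9. A swap of 7 with 9 or of 8 with 10, a single wrong label or an siRNA that failed stays open. Noise or lower depth of library 9 alone is argued against by the 19 of 19 called genes with the same direction in 10/8, although these genes are not independent of each other. A culture state shared by libraries 9 and 10 cannot be told apart from a shared FoxO3 siRNA effect, because both carry the label and each is 1 library; 5 of the called genes are in the joint siRNA list and all 5 went the same way in 4/3. An effect of FoxO3 siRNA on protein with its mRNA recovered is a further possibility that was not tested.

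Of the 15 cytokine and chemokine list members in the Wnt3a table, 14 had a larger Wnt3a ratio with H2O2 than without, as had 10 of the 11 with FPKM of 5 or more. Selection of the table on the 2/1 ratio raises 2/1 and so works against this pattern by construction, which the count of 14 cannot test. The extent of that opposing effect was not decided over the 75 genes with a 2/1 ratio of 1 or more. Of these, 50.7% were larger in 6/5, between the bounds of 50% and 60% set beforehand. Of the 53 with FPKM of 5 or more, a filter added after, 33 were larger. Scaling of the 6/5 pair cannot be told apart: 46 genes with FPKM of 10 or more and a 2/1 ratio under 0.58 had a median difference of -0.030, but their 2/1 ratios were inflated by selection, so the bound set beforehand was wrong and a shift of 6/5 could be hidden. An additive such as endotoxin in the Wnt3a preparation cannot be told apart for the 15 cytokine list members, since library 1 received diluting buffer and no library received the additive alone; the empty Wnt entry of library 5 adds to this. Interaction of Wnt3a with oxidative stress stays open as a hypothesis.

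Among single genes, the Wnt3a effect turned from above to below 0 with H2O2 for Gga3 (-1.20) and Cep131 (-1.07). Snhg9 was picked out by the same rule, but it is listed at 0 in library 6, a possible failed estimate, so its computed difference of -3.65 is not taken as an effect. The joint siRNA effect turned upwards with H2O2 for Sp140, by 1.18, and Wnk4, by 1.07, and downwards for Gemin4 (-1.24) and Il34 (-1.004). Gemin4 shares 89.8% of its exonic bases with Glod4 and was uncertain. The joint siRNA list holds only genes past the same absolute bound in both settings, so opposite signs there force a large difference. Of its 1637 genes, 387 went from above to below 0 and 383 from below to above. Genes of the Wnt3a list lie above 0 without H2O2 by selection, and 769 of its 1852 lay below 0 with H2O2. None of the opposite directions named here was tested.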

How the results depend on the processing

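The 2-fold counts depended strongly on settings, and the cause was not tested beyond what each setting removes. For 8/7, 9/7 and 10/7 the counts of 143, 186 and 148 became 281, 381 and 292 with a pseudocount of 0.1 FPKM, 44, 51 and 59 with 5 FPKM, 53, 86 and 64 at FPKM of 5 or more, 322, 546 and 357 with a size rule of 0.58, and 0, 19 and 0 by the authors' q. Settings chosen after seeing the data gave 49, 86 and 40 without FAIL rows and rows listed at 0, and 35, 70 and 31 without the left-out symbols. Dropping the filter on low values left the counts unchanged, which the pseudocount of 1 FPKM makes certain at 2-fold. Centring gave 143, 182 and 151, status OK only 97, 141 and 99, and library 8 as the control of library 10 gave 168. These stayed within 1.5 times. For Wnt3a the 46 genes past 2-fold in both settings became 131 and 19 with the 2 pseudocounts, 135 with a size rule of 0.58 and 29 at FPKM of 10 or more, and for joint siRNA the 3 genes became 56, 1 and 26 with the 2 pseudocounts and the size rule of 0.58. At FPKM of 1, 5 and 10 or more, the share with the same sign was 67.9%, 82.3% and 87.0% for Wnt3a and 59.2%, 83.3% and 86.4% for joint siRNA.

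The correlation of 8/7 with 9/7, 0.46, was 0.25 by Spearman, 0.49 at FPKM of 5 or more and 0.49 and 0.42 with the 2 pseudocounts, and 0.24 without FAIL rows, rows listed at 0 and left-out symbols. That of 8/7 with 10/7 was 0.39 by Spearman and 0.41 without those rows, and that of 9/7 with 10/7 was 0.43 by Spearman. Comparisons with no library in common, also chosen after seeing the data, gave 0.014 for 8/7 with 10/9 and 0.069 for 9/7 with 10/8 over all genes. With the mean in place of the median, 4 lists instead of 2 in 8/7, 8 instead of 10 in 9/7 (4 of the 10 and 4 others) and 3 instead of 7 in 10/7 (1 of the 7 and 2 others) lay outside the middle 95% of random lists, and the NRF2-driven list in 8/7 turned to 0.21, the Txnrd1 row listed at 0 being its largest member. Of the recomputations of the 19 list medians outside, 17 lay inside, 12 of them with the mean, and 96 lay outside in the same direction. Single genes were recomputed only for the 10 highest and 10 lowest of 8/7, 9/7 and 10/7. A pseudocount cannot change the sign of a ratio, but it changed sizes. With 0.1 FPKM, Cd55 in 9/7 went from 1.65 to 2.32 and Foxo1 in 8/7 from -0.94 to -1.09. Centring removed medians of -0.006, -0.017 and -0.016, too small to turn the sign of a ranked gene. Centring was not run on the 2 selected lists, which hold no unselected genes to centre on. Depth is unknown, and FPKM under 1 carries most of both selected lists.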

Other observations

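Cholesterol synthesis genes were below 0 in 18 of 19 members in 10/8, with a median of -0.27, and in 16 of 19 in 9/7, a pair with no library in common with it, with a median of -0.14, while 16 of 19 lay above 0 in 8/7. The ratios 10/8 and 8/7 share library 8 on opposite sides. A high level in library 8 alone would raise 8/7 and lower 10/8, here and in the interferon list below. Tubular injury genes were below 0 in 12 of 16 members in 9/7 and in 13 of 16 in 10/8, with medians of -0.20 and -0.14. Interferon-stimulated genes had 10/8 ratios below 0 in all 24 members and 10/9 ratios above 0 in 20 of 24, with medians of -0.56 and 0.31, so the library with both siRNAs lay between libraries 8 and 9. Of the 19 genes called by the authors in 9/7, 13 had the same direction in 8/7 as well, with a median along it of 0.15. Both ratios share library 7 and the genes were chosen on 9/7, so some agreement would arise without any siRNA effect.

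Taf9 had ratios of 1.31, 1.28 and 1.49 in 8/7, 9/7 and 10/7, and Gpr19 0.81, 0.83 and 0.84, so library 7, the control of all 3 ratios, stood apart for these genes. Gapdh was listed at 0 in library 7 in all 3 tables, and at 931, 841 and 1033 FPKM in libraries 8, 9 and 10. The microRNA row mmu-mir-703 was listed at 0 in library 10 only, with an FPKM of 40.2 in library 7.

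The medians of 5 further lists lay within the middle 95% of random lists in all 3 comparisons. Medians in 8/7, 9/7 and 10/7 were -0.02, 0.02 and -0.01 for mitochondrial respiration and fatty acid oxidation genes, 0.02, -0.06 and -0.0044 for glycolysis and hypoxia genes, -0.05, 0.07 and -0.03 for insulin and AKT pathway genes, -0.06, -0.01 and -0.03 for beta-catenin complex genes and 0.04, 0.08 and 0.03 for heat shock genes. Members past 0.58 in these lists, apart from Gapdh, were Ppara at 0.95 in 8/7, which had an FPKM of 1.01 in library 8, Pfkfb3 at -0.73 and Pdk1 at 0.60 in 9/7, and Hspb1 at -0.66 in 10/7.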
